A study of Mus musculus with 12 samples.

How the data were processed

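Gene expression was measured by RNA sequencing of total RNA in 12 libraries of mouse leukaemia cells, 3 for each of 4 treatments. The cells came from BALB/c bone marrow made to express mutant forms of the granulocyte colony-stimulating factor receptor CSF3R and of the transcription factor CEBPA by retroviral transfer. They were grown in IMDM medium with fetal bovine serum and kept for 24 h with the solvent DMSO, 50 nM ruxolitinib (an inhibitor of the kinases JAK1 and JAK2), 2 nM GSK-LSD1 (an inhibitor of the histone demethylase LSD1, encoded by Kdm1a) or both drugs together. RNA was taken up with a column kit for small samples, and the libraries were made by a sequencing company.

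The deposited table gives a normalised signal per gene and library: gene read counts that the authors divided by a factor for each library, with 1e-05 added to every value. After the constant was taken off, all values of a library lay within a tolerance of 0.01 of whole multiples of a single step, between 0.9865 and 1.027. The submitters' processing notes name STAR, DESeq2 and the genome builds mm10 and GRCm38, without versions or roles. The annotation, the counting program, the strandedness of the libraries and any filter are not stated there. The constant was taken off before further use, so a value listed at the constant alone was read as 0.

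The table held 24411 gene symbols, of which 7367 were at 0 in all 12 libraries. Among the symbols 27 had been turned into dates, and 2 stood there more than once. These entries stayed in the tests but were never named. Multiples of the step summed to between 8260995 and 8528400 per library, so depth hardly differed between libraries if these are reads. Because of the added constant, whole reads were not taken as recovered, and tests that need counts were not run. The 10 highest genes took 3.73% to 4.17% of a library. Pairs of replicates differed by 1.48 to 7.13 times the variance of counting alone (chi-square per degree of freedom), and the values above 5 were those with ruxolitinib replicate 2 or combination replicate 3.

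Genes with a mean value of at least 10 over the 12 libraries were tested, 11484 in all. A linear model with a mean per treatment was fitted to log2 of the value plus 1 with limma (version 3.58.1, R 4.3.3), with a variance trend, no weights and 8 residual degrees of freedom. The 3 treatments were compared with DMSO, the combination with each single drug, and GSK-LSD1 with ruxolitinib. The interaction compared the combination with the sum of both single effects on the log2 scale. An F-test asked for any difference among the 4 treatments. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p under 0.05 passed the test, with no limit on the fold change. Values are given as normalised read counts with mean ± SD (n = 3), and log2 fold changes with ± SE.

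A set of 29 gene lists with 507 genes was drawn up before the data were examined. They covered targets of both drugs, granulocyte and monocyte maturation, proliferation, metabolism, stress and markers of other cells of bone marrow. Of these, 27 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with all other genes, whereas fry asks whether a list's genes move, on balance, in a single direction. Member counts are given over all genes tested and adjusted over the list alone.

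Genes to name were chosen by a rule fixed at the same time. It took the 6 largest rises and 6 largest falls against DMSO (4 and 4 in the other comparisons) among genes past the test with a mean of at least 100 in the higher group, no overlap between the groups' libraries and no predicted gene symbol. It added the 3 members with the smallest p of each list that passed, and 15 genes of prior interest in the comparisons with DMSO. The text gives some of the genes so chosen, not all, and 3 are not reported here. Positions are from the GENCODE vM21 annotation of GRCm38, matched by symbol. Symbols do not tell apart overlapping genes or transcripts of the introduced genes, so the values of Csf3r and Cebpa could include reads from the retroviral copies.

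The procedure was tested on simulated data with the same depths and 200 changed genes in each of 5 draws. Against DMSO it found 34% of genes changed 1.2-fold, 84.8% at 1.5-fold and 92.8% at 2-fold, with 5.36% false calls. For the interaction it found 10.4%, 60.8% and 88.4%, with 5.42% false calls. Every simulated gene had the same variance beyond counting (dispersion 0.00245), and no simulated library stood apart or followed GC content. These shares may therefore not hold for the real libraries, above all in comparisons with ruxolitinib. The alternatives were other pseudocounts (0.25 and 5), no filter or a mean of at least 50, TMM scaling, quantile normalisation, the replicate number as a block, no variance trend, robust variance, a fit to the compared groups alone, and each library left out in turn. After the data had been seen, 3 more were added: leaving out ruxolitinib replicate 2 and combination replicate 3 together, array weights, and a correction that removed a smooth trend on transcript GC content from each library. GC content was known for 11053 of the tested genes (96.2%).

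The labels number the libraries of a treatment from 1 to 3 without saying that they came from separate cultures. The p-values therefore measure spread among samples that may be technical replicates.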

Results

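The series compared 4 treatments of mouse CEBPA/CSF3R mutant leukaemia cells after 24 h: DMSO, ruxolitinib, GSK-LSD1 and both drugs. Each treatment had 3 libraries, and the values of each library, in multiples of their step, summed to between 8260995 and 8528400. Treatment changed 4910 of 11484 tested genes (limma F-test). The first principal component held 54.7% of the variance and set libraries with GSK-LSD1 apart from those without it. On component 2 (11.1%), ruxolitinib replicate 2 at -19.7 and combination replicate 3 at -17.3 lay below the other libraries of their groups.

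**Figure D1:**
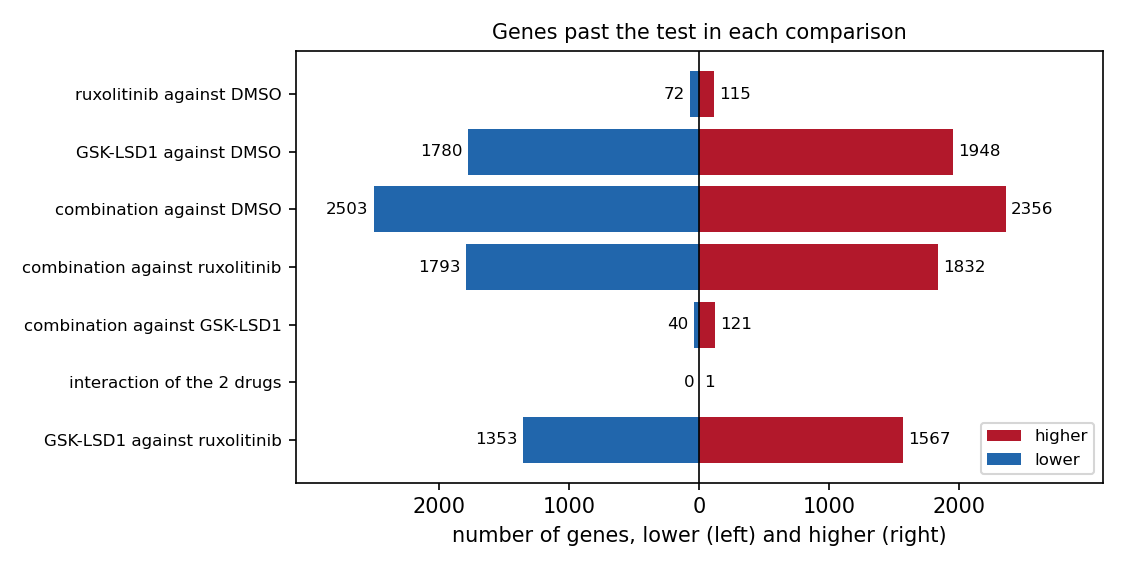
Number of genes past the test (adjusted p under 0.05, limma) in each comparison, lower to the left and higher to the right. Ruxolitinib changed 187 genes, GSK-LSD1 changed 3728 and the combination changed 4859 against DMSO.

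**Figure D2:**
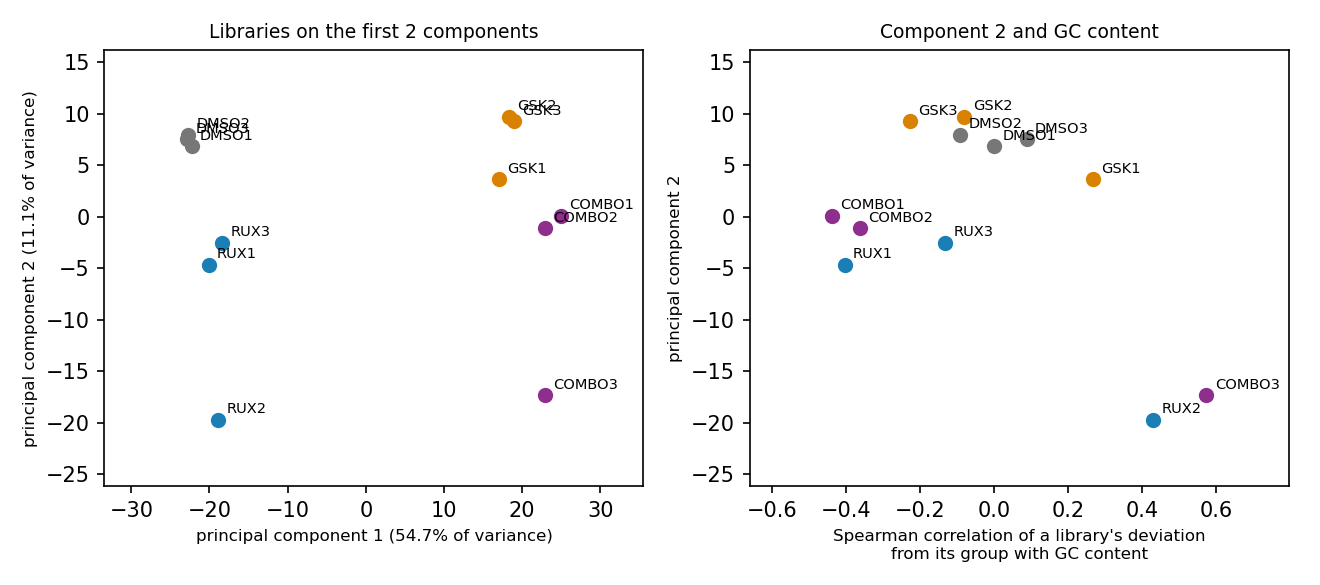
Left, the 12 libraries on principal components 1 and 2 of the log2 values, coloured by treatment. Right, component 2 against the Spearman correlation, across genes, of each library's deviation from its group mean with transcript GC content, which reached 0.43 in ruxolitinib replicate 2 and 0.573 in combination replicate 3.

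The first comparison asked what the JAK1/2 inhibitor ruxolitinib changed. After ruxolitinib, genes of the neutrophil granule were higher than after DMSO. Elane (neutrophil elastase; chromosome 10, 79886247 to 79888215, plus strand) rose from 137.6 ± 5.6 to 259.4 ± 52.2 normalised read counts (log2 fold change 0.89 ± 0.14 SE, adjusted p = 0.00251). Mpo (myeloperoxidase; chromosome 11, 87793581 to 87804413) rose from 6565 ± 169 to 10320 ± 1770 (0.64 ± 0.08, adjusted p = 0.000541). Prtn3 (proteinase 3), which overlaps Plppr3 on the other strand, rose by 0.59 ± 0.09 and Chil3, a chitinase-like protein of neutrophils and macrophages, by 0.61 ± 0.08. Of 10 primary granule genes 5 rose (7 rose and 1 fell adjusted over the list alone), with a mean change of 0.36 (camera adjusted p = 1.03e-05; adjusted p = 0.136 with an estimated correlation). Of 12 secondary and tertiary granule genes 3 rose (8 adjusted over the list alone), with a mean of 0.44 (adjusted p = 2.08e-06; adjusted p = 0.111 with an estimated correlation). Of 14 mast cell, basophil and eosinophil genes 1 rose (4 adjusted over the list alone; adjusted p = 0.00455, and adjusted p = 0.186 with an estimated correlation): Prss34, a basophil protease, at 0.73 ± 0.09. Aatk rose by 0.75 ± 0.13, while Ppic (a cyclophilin) at -0.76 ± 0.14 and Lrp12 at -0.48 ± 0.08 fell.

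Genes lower after ruxolitinib included some of lipid and sugar metabolism, growth and cytokine signalling, in lists that were all lost with an estimated correlation. Of 21 cholesterol biosynthesis genes 5 fell (10 adjusted over the list alone; mean -0.15, adjusted p = 2.08e-06, and adjusted p = 0.151 with an estimated correlation). Among them were Msmo1 at -0.32 and Cyp51 at -0.31. Of 15 glycolysis and hypoxia genes 2 fell (11 adjusted over the list alone; mean -0.32, adjusted p = 2.08e-06, and adjusted p = 0.111 with an estimated correlation): Bnip3 at -0.82 and the hexokinase Hk2 at -0.30. Of 17 STAT3/STAT5 target genes 2 fell, and the same 2 adjusted over the list alone: Il2ra, the interleukin-2 receptor alpha chain, at -0.47 and the cytokine Osm at -0.31 (adjusted p = 0.0192; adjusted p = 0.412 with an estimated correlation). The genes of prior interest Cish, Socs2, Socs3 and Pim1 had log2 values of -0.08, 0.03, -0.02 and 0.05, none past the test. Of 25 DNA replication genes 2 fell, Hells at -0.35 and Rrm2 at -0.29 (2 adjusted over the list alone; adjusted p = 0.000153, and adjusted p = 0.108 with an estimated correlation). Of 24 MYC target and ribosome biogenesis genes 1 fell (3 adjusted over the list alone; adjusted p = 0.000317, and adjusted p = 0.136 with an estimated correlation). Of 7 heat shock genes 2 fell (3 adjusted over the list alone; adjusted p = 0.00455, and adjusted p = 0.111 with an estimated correlation). No mitosis gene passed over all genes (2 fell adjusted over the list alone; adjusted p = 0.00455, and adjusted p = 0.111 with an estimated correlation). No ribosomal protein gene passed either way (list mean 0.09, adjusted p = 0.0168, and adjusted p = 0.535 with an estimated correlation). Among genes open to the naming rule, with a mean of at least 100 in the higher group, the largest other rises were Ngp (neutrophilic granule protein) at 1.13 ± 0.20, Kcnq1ot1, which lies antisense to Kcnq1, at 1.07 ± 0.25, and Igf2r, which overlaps Airn, at 0.69 ± 0.14. The largest other falls among these were Scd1 (stearoyl-CoA desaturase) at -0.58, the immediate early gene Egr1 at -0.55, the lactate transporter Slc16a3 at -0.53 and Eps8 at -0.50. Gfi1b rose by 0.32 (adjusted p = 0.0486), and Myc was at 0.03 (adjusted p = 0.876).

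In total ruxolitinib changed 187 genes, 115 higher and 72 lower (2012 at an unadjusted p under 0.05); 9 rose and 4 fell by at least 2-fold. Fold changes after ruxolitinib followed transcript GC content (Spearman's rho 0.415 across 11053 genes, which are not independent replicates). After the GC correction 294 genes passed, 145 higher and 149 lower, so the excess of rises was not kept. Without ruxolitinib replicate 2 and combination replicate 3, 317 genes passed and the mean change of the primary granule list was 0.31, that of the secondary and tertiary list 0.40. The count was 58 without DMSO replicate 1, 69 without DMSO replicate 2, 32 without DMSO replicate 3, 41 without ruxolitinib replicate 2, 121 without GSK-LSD1 replicate 2, 117 without GSK-LSD1 replicate 3 and 551 without combination replicate 3. Elane, Mpo, Prtn3, Chil3, Prss34, Aatk, Ppic and Lrp12 passed with any 1 library left out, and the other 20 of 28 genes that the naming rule chose and that passed did not. Of those, 20 were lost without DMSO replicate 3 (adjusted p of 0.0508 to 0.204), 11 without DMSO replicate 1 (0.0546 to 0.157) and 10 without DMSO replicate 2 (0.0531 to 0.166). On the treated side 8 were lost without ruxolitinib replicate 1 (0.0525 to 0.116), 15 without ruxolitinib replicate 2 (0.062 to 0.217) and 1 without ruxolitinib replicate 3 (0.0672). Libraries outside the comparison also decided calls, through the shared estimate of spread: 2 were lost without GSK-LSD1 replicate 1 (0.0546 to 0.0659), 4 without replicate 2 (0.0547 to 0.0727), 6 without replicate 3 (0.0517 to 0.0796) and 2 without combination replicate 2 (0.0526 to 0.0612). The STAT list was lost without DMSO replicate 3 (adjusted p = 0.0517) or ruxolitinib replicate 1 (0.356), and the ribosomal protein list without DMSO replicate 2 (0.11) or ruxolitinib replicate 2 (0.578).

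The second comparison asked what the LSD1 inhibitor GSK-LSD1 changed. After GSK-LSD1, genes held down by LSD1 and its partner repressors GFI1 and GFI1B were higher, with genes of monocytes and mature neutrophils. Gfi1b itself (chromosome 2, 28609450 to 28621982, minus strand) rose from 770 ± 54.9 to 4040 ± 143 normalised read counts (log2 fold change 2.39 ± 0.08, adjusted p = 7.82e-15). Gfi1 (chromosome 5, 107716657 to 107726036, minus strand) rose from 94.49 ± 4.02 to 347.7 ± 37.7 (1.86 ± 0.12, adjusted p = 1.13e-10). Of 13 genes repressed by LSD1 and GFI1 in myeloid cells 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a mean of 0.77 (adjusted p = 0.0001, and 0.0206 with an estimated correlation). Other lists here also hold 11 of this list's 15 genes, tested or not, so its result is not independent of theirs in any comparison. Csf1, the macrophage colony-stimulating factor, rose by 1.32 ± 0.11. Of 17 monocyte and macrophage genes 12 rose (13 adjusted over the list alone; mean 0.66, adjusted p = 8.15e-07, and 0.0124 with an estimated correlation), such as the lysosomal genes Ctss at 1.84 ± 0.13 and Psap at 0.69 ± 0.05, and Lgals3 at 0.88 ± 0.08. Of 17 mature neutrophil genes 11 rose (12 adjusted over the list alone; mean 0.52, adjusted p = 0.0001, and adjusted p = 0.0562 with an estimated correlation). Among them was the integrin gene Itgam, from 317.6 ± 29.3 to 458.7 ± 2.52 (0.53 ± 0.08).

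Growth genes moved the other way after GSK-LSD1. Of 24 MYC target and ribosome biogenesis genes 23 fell, and 23 adjusted over the list alone (mean -0.45, adjusted p = 1.77e-13, and 0.012 with an estimated correlation). Examples were the polyamine enzymes Srm at -0.71 ± 0.07 and Odc1 at -0.62 ± 0.07 and the nucleolar gene Nolc1 at -0.57 ± 0.06. Myc itself fell from 5527 ± 123 to 4332 ± 141 (-0.35 ± 0.07, adjusted p = 0.000634). Of 25 DNA replication genes 23 fell (24 adjusted over the list alone; mean -0.27, adjusted p = 2.67e-09, and 0.00808 with an estimated correlation), with Hells at -0.40, Mcm10 at -0.34 and Pcna at -0.32. Of 22 mitosis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; mean -0.12, adjusted p = 0.00622, and adjusted p = 0.0687 with an estimated correlation), with Ccna2 at -0.28 and Tpx2 at -0.19. Of 7 heat shock genes 5 fell (6 adjusted over the list alone; mean -0.31, adjusted p = 0.00173, and 0.0362 with an estimated correlation, or 0.0606 after the GC correction). Of 21 cholesterol genes 13 fell (14 adjusted over the list alone; adjusted p = 0.0001, and adjusted p = 0.157 with an estimated correlation). Of 15 glycolysis and hypoxia genes 7 fell (7 adjusted over the list alone; adjusted p = 0.00693, and adjusted p = 0.223 with an estimated correlation). Of 17 unfolded protein and amino acid stress genes 7 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.0266, and adjusted p = 0.131 with an estimated correlation), with the serine enzyme Psat1 at -0.34 and the asparagine synthetase Asns at -0.40. That list was lost without DMSO replicate 2 (adjusted p = 0.0548) or GSK-LSD1 replicate 3 (0.0609). Of 32 ribosomal protein genes 2 fell (1 adjusted over the list alone; adjusted p = 0.0215, and adjusted p = 0.455 with an estimated correlation), a call lost without DMSO replicate 3 (adjusted p = 0.054).

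Lists of interferon response and of 4 other blood lineages also passed after GSK-LSD1, and the 4 lineage lists were lost with an estimated correlation. Of 20 interferon-stimulated genes 7 rose and 1 fell, the same counts adjusted over the list alone (mean 0.36, adjusted p = 0.00237, and 0.0327 with an estimated correlation), with Gbp2 at 0.87, Ddx58 at 0.57 and Irf1 at 0.37. Of 5 dendritic cell and MHC class II genes 3 rose (3 adjusted over the list alone): Cd86 at 1.67 ± 0.20, the invariant chain Cd74 at 1.45 ± 0.19 and Ccr7 at 1.28 ± 0.17 (adjusted p = 0.00693; adjusted p = 0.0562 with an estimated correlation). Of 14 mast cell, basophil and eosinophil genes 8 rose (9 adjusted over the list alone; adjusted p = 0.00413, and adjusted p = 0.131 with an estimated correlation), such as the histamine-forming enzyme Hdc at 0.82 and the tryptase Tpsab1 at 2.40 from a mean of 5.643. Of 12 erythroid genes 5 fell (7 adjusted over the list alone; mean -0.60, adjusted p = 0.00304, and adjusted p = 0.293 with an estimated correlation), with Car2 at -1.25 ± 0.14 and Slc4a1, the red cell anion exchanger, at -1.86 ± 0.30. Of 14 genes of the LSD1 repressor complex 8 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 0.00693; adjusted p = 0.056 with an estimated correlation). Gfi1b and Gfi1 belong to that list too, with Phf21a at 0.48, whereas Kdm1a was at -0.05 ± 0.06 (adjusted p = 0.524). Of 6 lymphocyte genes 3 rose (4 adjusted over the list alone): Il2rb at 1.17, Rag1 at 0.52 and Klrb1c at 0.67 (adjusted p = 0.0435; adjusted p = 0.131 with an estimated correlation). The lymphocyte list was lost without DMSO replicate 2 (adjusted p = 0.0504), DMSO replicate 3 (0.0726), ruxolitinib replicate 1 (0.0525), GSK-LSD1 replicate 1 (0.12), combination replicate 1 (0.0514) or combination replicate 3 (0.0536). Klrb1c was lost without DMSO replicate 1 (0.0554) or 2 (0.131) or GSK-LSD1 replicate 1 (0.0663) or 2 (0.134).

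GSK-LSD1 changed 3728 genes in total, 1948 higher and 1780 lower. Rises reached further than falls, since 299 genes rose and 27 fell by at least 2-fold. Among genes with a mean of at least 100 in the higher group, the largest rises were Moxd1 at 3.44 ± 0.24 (33.12 ± 8.3 to 363.3 ± 20.9), the kinase gene Cdc42bpb at 3.11 ± 0.12, Pigz (15.25 ± 0.519 to 129.3 ± 13.4) and Maged1 at 2.89 ± 0.13. The serine carboxypeptidase Scpep1, which overlaps Scpep1os, followed at 2.89 ± 0.18, and Id3, an inhibitor of basic helix-loop-helix factors, at 2.87 ± 0.26. The largest falls at that level were Ms4a3, a gene of granulocyte-monocyte progenitors, at -1.33 ± 0.13, then Car2, Egr1 at -1.23 ± 0.10, Rprm at -1.19 ± 0.09, Gpr25 at -1.16 ± 0.14 and Ccnb1ip1 at -1.08 ± 0.17, which overlaps the RNA gene Rpph1. Jak1, Jak2, Csf3r, Cebpa and Spi1 had log2 values of 0.14, 0.08, 0.01, -0.07 and 0.23, none past the test. The granule lists did not pass: 2 primary granule genes rose and 4 fell (adjusted p = 0.136), and 5 of 12 secondary and tertiary granule genes rose (adjusted p = 0.132).

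The third comparison asked what both drugs changed together. After the combination, all 12 secondary and tertiary granule genes were higher than after DMSO, with a mean of 1.24 (12 adjusted over the list alone; adjusted p = 1.17e-08, and 0.0375 with an estimated correlation, or 0.0572 after the GC correction). Mmp8, neutrophil collagenase (chromosome 9, 7558456 to 7568485, plus strand), rose from 2074 ± 158 to 8019 ± 459 normalised read counts (1.95 ± 0.07, adjusted p = 1.88e-14). Lysozyme (Lyz2) rose from 454.8 ± 77.2 to 1152 ± 52.5 (1.35 ± 0.10) and Chil3 from 358.4 ± 21.1 to 744.2 ± 30.6 (1.05 ± 0.08). Of 17 mature neutrophil genes 15 rose (15 adjusted over the list alone; mean 0.98, adjusted p = 3.75e-09, and 0.015 with an estimated correlation). Among these were the annexin Anxa1 at 1.17 ± 0.08 and Itgam at 1.09 ± 0.08, from 317.6 ± 29.3 to 675.3 ± 62.5. Of 17 monocyte and macrophage genes 13 rose and 1 fell, the same adjusted over the list alone (mean 0.89, adjusted p = 1.72e-06, and 0.015 with an estimated correlation), with Ctss at 1.91 and Psap at 1.09. Of 13 LSD1/GFI1-repressed genes 11 rose and 1 fell, the same adjusted over the list alone (mean 0.99, adjusted p = 5.19e-05, and 0.015 with an estimated correlation), with Gfi1b at 2.64, Gfi1 at 2.13 and Csf1 at 1.60.

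All 24 MYC target and ribosome biogenesis genes fell after the combination (24 adjusted over the list alone; mean -0.60, adjusted p = 6.42e-14, and 0.0108 with an estimated correlation), such as Srm at -0.86 ± 0.07 and the chaperonin Hspd1, which overlaps Hspe1, at -0.82 ± 0.07. Of 25 DNA replication genes 24 fell (24 adjusted over the list alone; mean -0.35, adjusted p = 6.71e-10, and 0.0065 with an estimated correlation). Of 7 heat shock genes 6 fell (7 adjusted over the list alone; mean -0.42, adjusted p = 0.000734, and 0.0287 with an estimated correlation, or 0.0564 after the GC correction). Of 22 mitosis genes 12 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.0877 with an estimated correlation). Of 21 cholesterol genes 14 fell (14 adjusted over the list alone; mean -0.31, adjusted p = 1.33e-05, and adjusted p = 0.123 with an estimated correlation), with Lss at -0.71 and Cyp51 at -0.52. Of 15 glycolysis and hypoxia genes 9 fell (9 adjusted over the list alone; mean -0.37, adjusted p = 0.000406, and adjusted p = 0.123 with an estimated correlation), with Pfkp at -0.59, the glucose transporter Slc2a1 at -0.54 and Ldha at -0.53. Of 12 MAPK feedback genes 7 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.0473; adjusted p = 0.246 with an estimated correlation). Egr1 was at -1.55 and Spred1 at -0.52, and Etv4 fell from 171.4 ± 15.6 to 84.57 ± 19.5. The MAPK list was lost without DMSO replicate 2 (adjusted p = 0.0688) or 3 (0.0593) or combination replicate 1 (0.0788) or 2 (0.0627). It was also lost with the replicate block (0.0566) or a filter at a mean of at least 50 (0.0798).

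After the combination, 7 of 20 interferon-stimulated genes rose and 1 fell, the same adjusted over the list alone (mean 0.30, adjusted p = 0.0123, and adjusted p = 0.0526 with an estimated correlation). Of 14 LSD1 repressor complex genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.087 with an estimated correlation). Of 5 dendritic cell and MHC class II genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0232, and adjusted p = 0.087 with an estimated correlation), with Cd86 at 1.65. Of 14 mast cell, basophil and eosinophil genes 8 rose (8 adjusted over the list alone; adjusted p = 0.00552, and adjusted p = 0.123 with an estimated correlation). Of 12 erythroid genes 7 fell (7 adjusted over the list alone; mean -0.49, adjusted p = 0.0268, and adjusted p = 0.435 with an estimated correlation), a call lost without combination replicate 1 (adjusted p = 0.0723) or 2 (0.103). Relative to the DMSO mean the erythroid list lay at -0.64 and -0.78 in these 2 libraries but at -0.04 in combination replicate 3.

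In all, the combination changed 4859 genes, 2356 higher and 2503 lower, with 451 rises and 33 falls of at least 2-fold. At a mean of at least 100 in the higher group, the largest rises were Fstl1 at 3.73 ± 0.24 (10.62 ± 4.54 to 145 ± 10.3), Cdc42bpb at 3.19 ± 0.12, Id3 at 3.05 ± 0.26, Scpep1 at 3.02 ± 0.18, Kctd14 at 2.97 ± 0.13 and Maged1 at 2.89 ± 0.13. The largest falls reported here at that level were Egr1, Ccnb1ip1 at -1.52, Rprm at -1.31, Car2 at -1.15 and the transporter Slco2b1 at -1.11. Spi1, encoding the myeloid factor PU.1, rose by 0.47 ± 0.10 (adjusted p = 0.000769) and Myc fell by 0.32 on the log2 scale (adjusted p = 0.00106). Jak1 rose by 0.18 (adjusted p = 0.0215) and Socs2 fell by 0.19 on the log2 scale (adjusted p = 0.0138). Jak1 was lost without DMSO replicate 1 (adjusted p = 0.051) or 2 (0.1) or combination replicate 1 (0.0917) or 2 (0.0688), and Socs2 without DMSO replicate 1 (0.0759). Kdm1a, Jak2, Csf3r, Cebpa, Cish, Socs3 and Pim1 did not pass, at -0.13, 0.03, 0.19, 0.04, 0.10, 0.08 and 0.02.

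**Figure D3:**
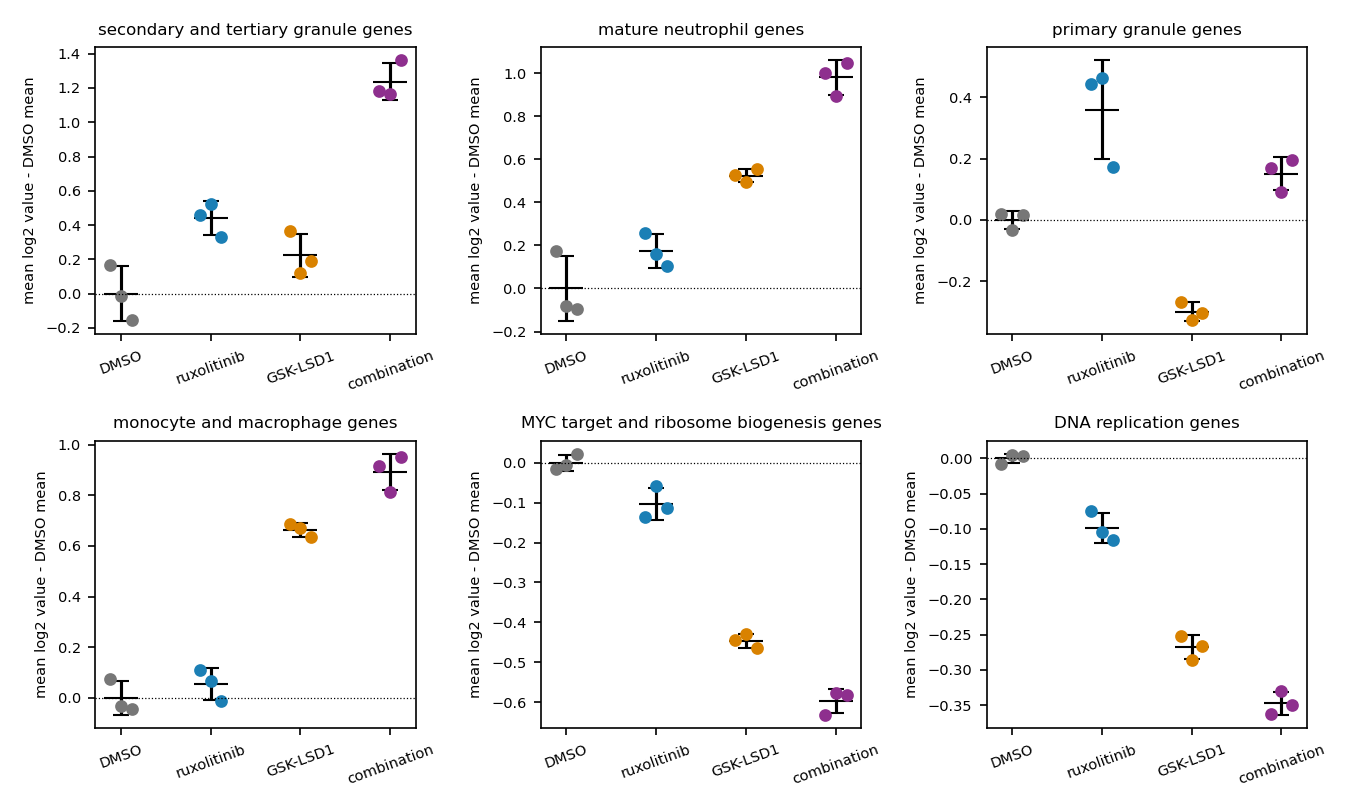
Mean log2 value of the members of 6 gene lists in each library, relative to the DMSO mean. Points are libraries, and bars give mean and SD of 3 libraries. Secondary and tertiary granule genes lay at a mean of 0.44 after ruxolitinib, 0.23 after GSK-LSD1 and 1.24 after the combination.

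**Figure D4:**
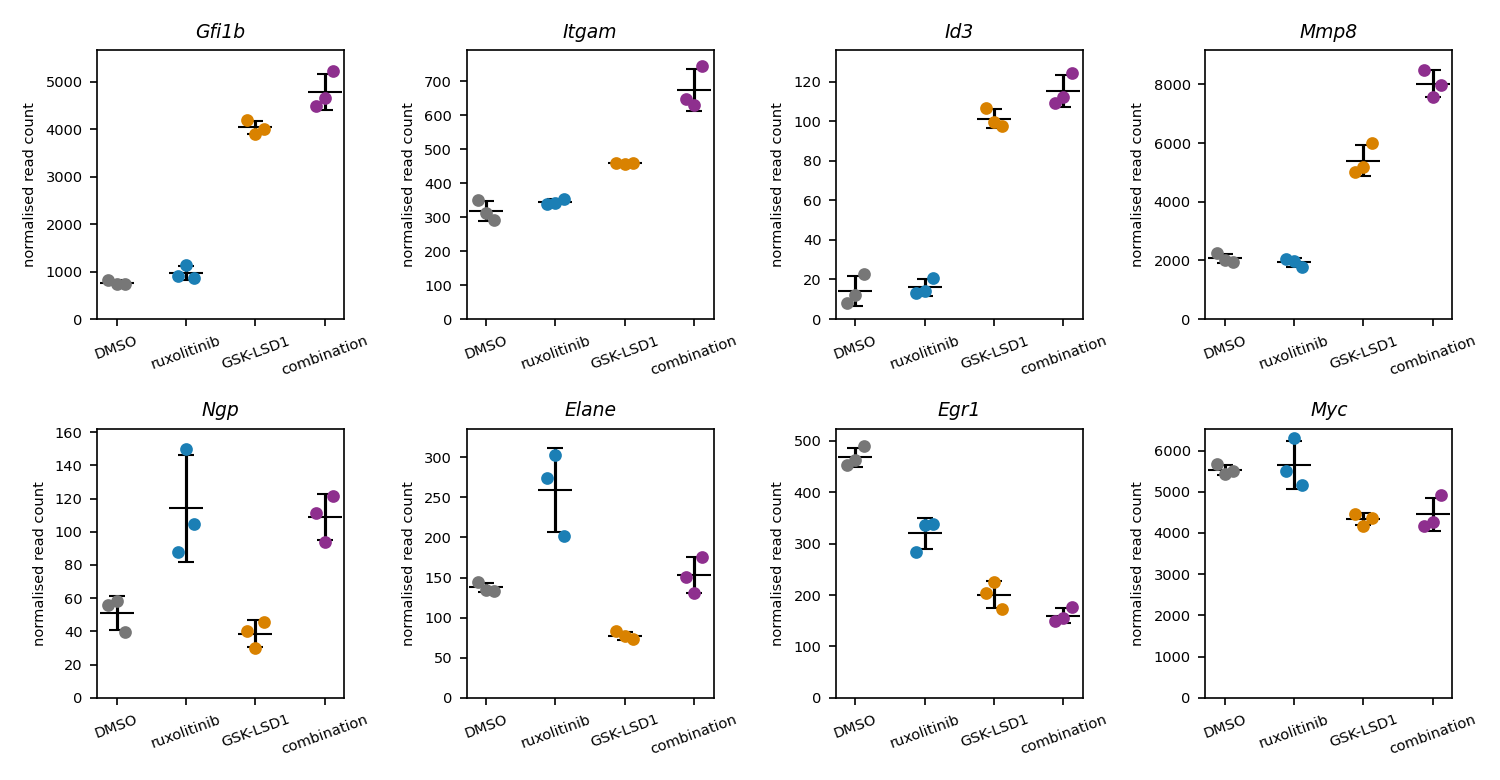
Normalised read counts of 8 genes in the 12 libraries, with mean and SD of 3 libraries per treatment. Mmp8 and Gfi1b were highest in the 3 combination libraries, and Elane was highest in the 3 ruxolitinib libraries.

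The comparison of the combination with ruxolitinib showed what GSK-LSD1 added in cells given ruxolitinib. Monocyte and neutrophil genes were higher again: 13 of 17 monocyte and macrophage genes rose and 1 fell, the same adjusted over the list alone (mean 0.84, adjusted p = 2.11e-08, and 0.00648 with an estimated correlation). Of 17 mature neutrophil genes 14 rose (15 adjusted over the list alone; mean 0.81, adjusted p = 2.13e-09, and 0.0101 with an estimated correlation). Mmp8 rose by 2.05 ± 0.07, the haptoglobin gene Hp by 1.14 ± 0.11 and Lyz2 by 1.08 ± 0.10. They were among 8 of 12 secondary and tertiary granule genes that rose (10 adjusted over the list alone; mean 0.80, adjusted p = 1.07e-06, and adjusted p = 0.0656 with an estimated correlation). Of 13 LSD1/GFI1-repressed genes 11 rose and 1 fell, the same adjusted over the list alone (adjusted p = 2.62e-06, and 0.00821 with an estimated correlation). Of 20 interferon-stimulated genes 10 rose, 10 adjusted over the list alone (adjusted p = 0.000146, and 0.0101 with an estimated correlation). Of 24 MYC target genes 23 fell (23 adjusted over the list alone; mean -0.49, adjusted p = 1.72e-14, and 0.00648 with an estimated correlation). Of 25 DNA replication genes 22 fell (23 adjusted over the list alone; mean -0.25, adjusted p = 2.11e-08, and 0.00648 with an estimated correlation).

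Further lists passed in that comparison. Of 14 LSD1 repressor complex genes 5 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.022; adjusted p = 0.0756 with an estimated correlation). Of 5 dendritic cell and MHC class II genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0337, and adjusted p = 0.112 with an estimated correlation). Of 12 erythroid genes 7 fell (9 adjusted over the list alone; adjusted p = 0.00189, and adjusted p = 0.324 with an estimated correlation), again little in combination replicate 3. Of 7 heat shock genes 4 fell (5 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.0634 with an estimated correlation). Of 21 cholesterol genes 7 fell and 1 rose, the same adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.338 with an estimated correlation), a call lost without ruxolitinib replicate 3 (adjusted p = 0.0962). Of 17 unfolded protein and amino acid stress genes 8 fell (8 adjusted over the list alone; adjusted p = 0.0323, and adjusted p = 0.152 with an estimated correlation), lost without combination replicate 2 (adjusted p = 0.0506). Of 32 ribosomal protein genes 7 fell (7 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.371 with an estimated correlation), lost without ruxolitinib replicate 2 (adjusted p = 0.0942). In total 3625 genes differed, 1832 higher and 1793 lower, with 364 rises and 26 falls of at least 2-fold. With a mean of at least 100 in the higher group, the largest rises were Moxd1 at 3.77, Maged1 at 3.32, Fstl1 at 3.09 and Cdc42bpb at 3.06, and the largest falls Car2 at -1.24, Rprm at -1.23, Ccnb1ip1 at -1.22 and Ms4a3 at -1.07.

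The comparison of the combination with GSK-LSD1 showed what ruxolitinib added in cells given GSK-LSD1. Granule genes stood out: 11 of 12 secondary and tertiary granule genes rose (11 adjusted over the list alone; mean 1.01, adjusted p = 9.12e-26, and 0.00812 with an estimated correlation). Ngp rose by 1.49 ± 0.20, the neutrophil surface gene Cd177 by 1.01 ± 0.12, Chil3 by 1.00 ± 0.08 and Hp by 0.96 ± 0.11, and Lyz2 from 565.5 ± 38.5 to 1152 ± 52.5. Of 17 mature neutrophil genes 8 rose (8 adjusted over the list alone; mean 0.46, adjusted p = 1.47e-10, and 0.0211 with an estimated correlation), with the leukotriene receptor Ltb4r1 at 1.01 ± 0.14, Anxa1 at 0.72 and S100a8 at 0.68. Of 10 primary granule genes 6 rose (6 adjusted over the list alone; mean 0.45, adjusted p = 1.25e-08, and adjusted p = 0.0661 with an estimated correlation), with Mpo at 0.77, Prtn3 at 0.77 and cathepsin G (Ctsg) at 0.75. No MYC target gene passed over all genes, but 11 of 24 fell adjusted over the list alone (mean -0.15, adjusted p = 5.41e-08, and 0.0445 with an estimated correlation). The same held for 1 of 25 DNA replication genes (mean -0.08, adjusted p = 0.000729, and 0.0445 with an estimated correlation), a list lost with an estimated correlation after the GC correction (adjusted p = 0.123).

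Il2ra fell by 0.53 and Osm by 0.34 on the log2 scale, 2 of 17 STAT3/STAT5 target genes (4 fell adjusted over the list alone; adjusted p = 0.00828, and adjusted p = 0.385 with an estimated correlation). That list was lost without combination replicate 1 (adjusted p = 0.0719) or 2 (0.0759). Of 13 LSD1/GFI1-repressed genes 2 rose, Cebpe at 0.79 and Itgam at 0.55 (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.00586, and adjusted p = 0.0661 with an estimated correlation). Of 17 monocyte and macrophage genes 2 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.00773, and adjusted p = 0.104 with an estimated correlation), with Psap at 0.40 and Ly6c2, which is similar in sequence to Ly6c1, at 1.77. Of 12 MAPK feedback genes 1 fell, Etv4 at -0.64 (3 adjusted over the list alone; adjusted p = 0.0289, and adjusted p = 0.315 with an estimated correlation). The MAPK list was lost without GSK-LSD1 replicate 1 (adjusted p = 0.138) or combination replicate 1 (0.181) or 2 (0.0711), and with no filter (0.0879). No cholesterol gene passed either way (list mean -0.10, adjusted p = 0.00733, and adjusted p = 0.409 with an estimated correlation). This list was lost without GSK-LSD1 replicate 1 (adjusted p = 0.094) or combination replicate 2 (0.0759). No glycolysis and hypoxia gene passed over all genes (4 fell adjusted over the list alone; adjusted p = 0.00237, and adjusted p = 0.254 with an estimated correlation). No heat shock gene passed either way (adjusted p = 0.0381; adjusted p = 0.15 with an estimated correlation). The heat shock call was lost without ruxolitinib replicate 1 (adjusted p = 0.0542), GSK-LSD1 replicate 1 (0.094), combination replicate 1 (0.0719) or combination replicate 3 (0.151).

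In this comparison 161 genes differed, 121 higher and 40 lower (1407 at an unadjusted p under 0.05), with 12 rises and 3 falls of at least 2-fold. The other named falls were Tnfrsf8 at -0.82 ± 0.13 and Nhp2l1 at -0.61 ± 0.16, a symbol without a position in the annotation used. Fold changes followed transcript GC content (Spearman's rho 0.26 across 11053 genes, which are not independent replicates). With ruxolitinib replicate 2 and combination replicate 3 left out, 270 genes differed, with a mean of 0.95 for the secondary and tertiary granule list. The count was 97 without GSK-LSD1 replicate 1, 83 without GSK-LSD1 replicate 2 and 102 without GSK-LSD1 replicate 3. Etv4 was lost without GSK-LSD1 replicate 1 (adjusted p = 0.0668) or 2 (0.126) or combination replicate 1 (0.0987). Nhp2l1 was lost without any of 9 libraries (adjusted p of 0.0569 to 0.213): DMSO replicates 1, 2 and 3, ruxolitinib replicates 1 and 3, GSK-LSD1 replicates 1, 2 and 3 and combination replicate 3.

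The interaction asked whether the effect of both drugs differed from the sum of the single effects on the log2 scale. Mmp8 was the single gene past the test, higher than the sum by 0.68 ± 0.11 (adjusted p = 0.0236). It stood at 2074 ± 158 after DMSO, 1932 ± 148 after ruxolitinib, 5405 ± 528 after GSK-LSD1 and 8019 ± 459 after the combination. At an unadjusted p under 0.05 there were 534 genes. The 12 secondary and tertiary granule genes were above the sum by a mean of 0.57 (1 past the test and 9 adjusted over the list alone; adjusted p = 7.92e-15, and 0.048 with an estimated correlation). The 17 mature neutrophil genes were above it by 0.28 (0 past the test and 5 adjusted over the list alone; adjusted p = 4.73e-08, and 0.048 with an estimated correlation). After the GC correction both lists were lost with an estimated correlation (adjusted p = 0.0739 and 0.0921). With fry only 1 list passed for the interaction, so the granule and neutrophil lists did not both pass there. Other lists that passed did so by smaller means. LSD1/GFI1-repressed genes were at 0.16 (adjusted p = 0.0297; adjusted p = 0.169 with an estimated correlation) and monocyte and macrophage genes at 0.17 (adjusted p = 0.0108; adjusted p = 0.166 with an estimated correlation). Mitosis genes were at 0.07 (adjusted p = 0.0127; adjusted p = 0.166 with an estimated correlation), cholesterol genes at 0.05 (adjusted p = 0.0191; adjusted p = 0.52 with an estimated correlation). Mast cell, basophil and eosinophil genes were below the sum, at -0.20 (adjusted p = 0.00878; adjusted p = 0.184 with an estimated correlation). No member of these 5 lists passed over all genes, and adjusted over the list alone 1 LSD1/GFI1-repressed gene was above the sum and 1 mast cell, basophil and eosinophil gene below it.

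Mmp8 was lost without DMSO replicate 1 (adjusted p = 0.207), DMSO replicate 2 (0.0858), ruxolitinib replicate 3 (0.126), GSK-LSD1 replicate 1 (0.115), GSK-LSD1 replicate 2 (0.199) or combination replicate 1 (0.115). In each of these fits 0 genes passed, and 2 passed without DMSO replicate 3, ruxolitinib replicate 1 or ruxolitinib replicate 2. The number of lists was 3 without combination replicate 3. The LSD1/GFI1 list was lost without DMSO replicate 1 (adjusted p = 0.063), DMSO replicate 2 (0.0508), ruxolitinib replicate 3 (0.153) or combination replicate 3 (0.172). The monocyte list (0.0985) and the mast cell list (0.0628) were lost without combination replicate 3. The mitosis list was lost without DMSO replicate 2 (0.0508), ruxolitinib replicate 1 (0.0644) or combination replicate 2 (0.0625). The cholesterol list was lost without DMSO replicate 3 (0.216), ruxolitinib replicate 1 (0.0821), ruxolitinib replicate 2 (0.133), GSK-LSD1 replicate 3 (0.152) or combination replicate 3 (0.19).

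Set directly against ruxolitinib, GSK-LSD1 left 2920 genes different, 1567 higher and 1353 lower, with 288 rises and 36 falls of at least 2-fold. For genes with a mean of at least 100 in the higher group, the largest rises were Moxd1 at 4.65 ± 0.24, Maged1 at 3.32 ± 0.13, the WNT inhibitor Dkk1 at 3.08 ± 0.15 and Cdc42bpb at 2.99 ± 0.12. The largest falls at that level were Ms4a3 at -1.72 ± 0.13, Elane at -1.71 ± 0.14, Ngp at -1.53 ± 0.20 and Car2 at -1.34 ± 0.14.

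Each drug's effect was set beside its effect in the presence of the other, in comparisons that share no library. Of the 3728 genes that GSK-LSD1 changed alone, 3650 (97.91%) had the same sign with ruxolitinib present and 2649 passed there too. The fold changes correlated across all tested genes (r = 0.852, rho = 0.792; genes are not independent replicates), and the median ratio among genes past the test was 0.899. Of the 187 genes that ruxolitinib changed alone, 175 (93.58%) had the same sign with GSK-LSD1 present and 44 passed there too (r = 0.387, rho = 0.426 across genes, median ratio 0.575). However, ruxolitinib replicate 2 stands in the first of these ruxolitinib comparisons and combination replicate 3 in the second. Their residuals correlated at 0.276 (highest other 0.215), and fold changes followed GC content in both comparisons (rho 0.415 and 0.26). Part of the agreement for ruxolitinib could come from these libraries. Both median ratios are over genes chosen for passing without the other drug, which alone can pull them under 1. They cannot show that an effect was weaker with the other drug present. Ruxolitinib and GSK-LSD1 both changed 131 genes against DMSO: 77 rose with either drug, 28 fell with either and 26 went opposite ways. Independent calls would give 19.5 shared rises and 11.2 shared falls, but both comparisons use the same 3 DMSO libraries. Unchanged groups simulated against those libraries shared 0 calls on average, with a correlation of 0.5 against 0.285 observed and a covariance of 0.0104 against 0.0227. Groups without any change have hardly any calls to share, so that 0 cannot show how far shared controls raise the overlap of real calls. The 3 control libraries cannot be divided to give each drug its own. The 105 genes changed the same way by either drug became 31 without DMSO replicate 1, 38 without DMSO replicate 2, 14 without DMSO replicate 3, 22 without ruxolitinib replicate 2, 54 without GSK-LSD1 replicate 2, 57 without GSK-LSD1 replicate 3 and 313 without combination replicate 3.

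**Figure D5:**
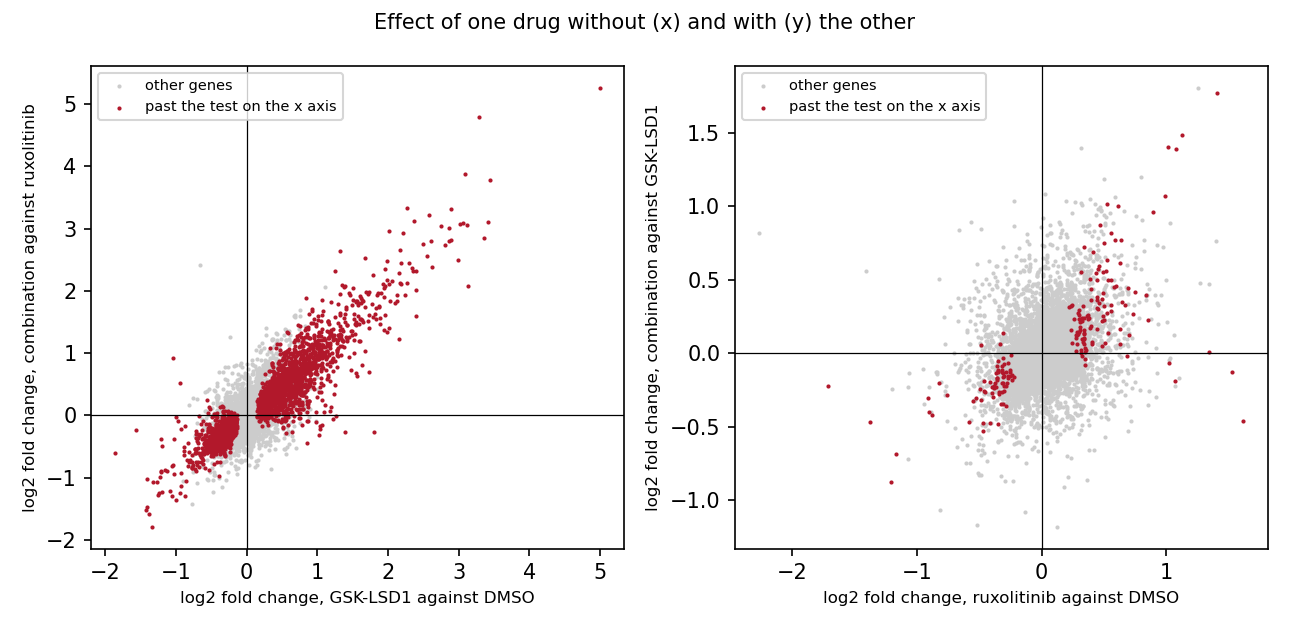
Each gene's log2 fold change for GSK-LSD1 (left) and ruxolitinib (right), without the other drug on the x axis and with it on the y axis. Red points passed the test on the x axis, of which 3650 of 3728 on the left and 175 of 187 on the right had the same sign on both axes.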

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

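Of the tests here, those of library depth, of low genes, of GC content for the granule list, of its label assignments and of residual arrangements were chosen only after the result was seen, as were the fits without ruxolitinib replicate 2 and combination replicate 3, with array weights and with a GC correction.

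The interaction test singled out genes whose response to one drug differed with the other present. Mmp8 lay above the sum of the single effects by 0.675 on the log2 scale, the secondary and tertiary granule list by a mean of 0.573, and the mature neutrophil list by 0.283. Smaller differences were those of the monocyte and macrophage list at 0.174, the LSD1/GFI1-repressed list at 0.161, the mitosis list at 0.068 and the cholesterol list at 0.05. The mast cell, basophil and eosinophil list differed from the sum by -0.198.

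All 12 secondary and tertiary granule genes had a positive interaction, such as Lyz2 at 0.76, Hp at 0.71 and Chil3 at 0.39. Members near the floor of the log scale did not account for it (0.558 over the 8 members with a mean of at least 100). Nor did transcript GC content (0.586 after the correction, adjusted p = 0.0739 with an estimated correlation) or the pair of libraries apart (0.553 without them; camera adjusted p = 5.18e-10, and 0.135 with an estimated correlation). Exchanges of ruxolitinib and control labels, within libraries with or without GSK-LSD1, carry ruxolitinib's own effect into the interaction, so residuals around additive effects were rearranged instead, only after those exchanges had been seen. Of 100 arrangements 1, the real one, was as large (highest other 0.474). Since the list had been chosen for its interaction, the largest mean of any of 27 lists was then taken. Again 1 of 100 was as large (highest other 0.499), and 1 to 3 of 100 with each library left out. That argues against a chance arrangement of the residuals. It cannot tell a joint action of both drugs from differences between cultures, since the libraries of a treatment may be technical replicates. A joint action on granule genes remains a hypothesis found and tested in the same 12 libraries.

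The label exchanges, first read as leaving chance open, cannot decide on it. For the granule list 23 of 100 assignments gave a mean as large in size (highest other 1.256), but additive drug effects alone, exchanged in the same way, reached 0.968. For the interaction counts 10 of 100 gave as many genes as the real 1 (highest other 75) and 20 as many lists as the real 7 (highest other 11). The 3 assignments with the most genes, 75, 61 and 22, were among the 10 in which additive effects reached 0.968, a product of the exchange itself. With the residuals rearranged, 1 of 100 arrangements, the real one, gave as many genes (highest other 0) and 4 as many lists (highest other 8). Each library was also left out and the other 11 rearranged. Where the real fit still had at least 1 gene, 2 to 8 of 100 arrangements gave as many genes. Where it had 0, any arrangement has as many, so those fits cannot decide. For lists 1 to 29 of 100 arrangements gave as many, so chance stays open for both counts. For any difference among the 4 treatments, 1 of 100 assignments, the real one, reached 4910 genes (highest other 621). That argues against a chance match of libraries and labels. It cannot tell treatment from differences between cultures, since the libraries of a treatment may be technical replicates.

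The 6 libraries of a pair of treatments allow 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes in each pair: 187 for ruxolitinib and DMSO, 3728 for GSK-LSD1 and DMSO, 4859 for the combination and DMSO, 3625 for the combination and ruxolitinib, 161 for the combination and GSK-LSD1 and 2920 for GSK-LSD1 and ruxolitinib, with 0 as the highest other in each. For lists the real value and the highest other were 11 and 8, 17 and 13, 16 and 14, 14 and 9, and 12 and 5, in the order of the first 5 pairs.

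Ruxolitinib replicate 2 and combination replicate 3 lay apart from their groups, and each carries ruxolitinib. Library depth did not account for it, since their totals were within 0.93% of the other libraries of their groups (-0.93% in ruxolitinib replicate 2). Their deviations followed transcript GC content across genes, with a Spearman correlation of 0.43 in ruxolitinib replicate 2 and 0.573 in combination replicate 3. The other 10 libraries lay at -0.437 to 0.266, but deviations within a group depend on each other, so this range is no independent reference. Its low end, -0.437, was combination replicate 1, of the same group as combination replicate 3. GC content is a candidate explanation. Transcript length cannot be told apart, with -0.288 and -0.302 against -0.368 to 0.343 in the others. After the GC correction both were still the lowest of their groups on component 2, at -15.3 and -10.6, and no biological explanation was tested.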

How the results depend on the processing

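Leaving out ruxolitinib replicate 2 with combination replicate 3, array weights and the GC correction were chosen only after the data had been seen. The 4 large comparisons and the F-test stayed within 1.5 times their counts under all alternatives. No result of a gene chosen by the naming rule changed direction where it passed the test in the main fit or in the alternative. Among results past it in neither fit, some changed sign (8 of them after the GC correction). Of 220 results of these genes past the test in the main fit, 30 were lost under at least 1 of 25 alternatives. The other 190 passed under every alternative that tested them. Some genes were missing from a fit, as with the filter at a mean of at least 50. Small changes were often missed: on simulated data with 3 libraries per group 34% of 1.2-fold changes were found. The edgeR and DESeq2 tests planned for whole counts were not run. Each left-out fit kept at least 2 libraries per treatment. Replicate numbers do not pair the samples (4 of 12 libraries matched best to their own number), so the replicate block is only a check. Except for fewer samples or genes, the cause was not tested.

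Ruxolitinib against DMSO (187 genes, 61.5% higher) gave 98 without the filter, 112 with the replicate block, 43 without the variance trend, 82 with only both groups compared, 317 (47% higher) without both libraries, 300 (52.7%) with array weights and 294 (49.3%) after GC correction. The combination against GSK-LSD1 (161, 75.2% higher) gave 93 without the trend, 270 (59.3%) without both libraries, 427 (57.1%) with weights and 283 (63.3%) after GC correction. The interaction (1 gene) gave 0 with no filter, quantile normalisation, the block or no trend, 3 without both libraries, 5 with weights and 4 after GC correction. The 105 genes changed the same way by both drugs became 48 without the filter, 57 with the block, 24 without the trend, 204 without both libraries, 196 with weights and 175 after GC correction. Sign agreement for GSK-LSD1 (97.9%) was 96.4% without both libraries and 96.2% with weights.

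With an estimated correlation the lists past the test went from 11 to 0 for ruxolitinib, 17 to 6 for GSK-LSD1, 16 to 7 for the combination, 14 to 6 for the combination against ruxolitinib, 12 to 4 against GSK-LSD1 and 7 to 2 for the interaction. Fry gave 23 for the combination against ruxolitinib and 1 for the interaction, which had 3 without the filter.

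With each library left out in turn, genes ranged from 32 to 551 for ruxolitinib, 2736 to 4209 for GSK-LSD1, 4025 to 5172 for the combination, 2872 to 3833 for the combination against ruxolitinib, 83 to 226 against GSK-LSD1, 1973 to 3529 for GSK-LSD1 against ruxolitinib, 0 to 2 for the interaction and 4125 to 5327 for the F-test. Lists ranged from 10 to 13, 15 to 19, 14 to 18, 13 to 15 and 9 to 12 in the first 5 of these, and from 3 to 8 for the interaction. Sign agreement ranged from 96.4% to 98.8% for GSK-LSD1 and from 88.2% to 100% for ruxolitinib, and the shared genes from 14 to 313.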

Other observations

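The tests of lymphocytes were chosen only after the values had been seen, as were the genes named with them. The lists that passed in no comparison also held genes that moved. Against DMSO the combination raised 5 of 15 stem and progenitor genes and lowered 5, the same adjusted over the list alone (adjusted p = 0.624). Of 9 megakaryocyte and platelet genes 4 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0506), and of 14 immediate early genes 7 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.217). Of 16 p53 target genes 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.545). Of 10 NF-kB and inflammatory cytokine genes 4 rose, 4 adjusted over the list alone (adjusted p = 0.217). Of 5 drug target genes 1 rose, Jak1 (1 adjusted over the list alone; adjusted p = 0.689). Of 2 tested stromal and endothelial genes 1 rose (2 adjusted over the list alone), and the list was too small to test. No mitochondrially encoded gene was found in the table under its symbol.

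After GSK-LSD1 several genes known from T and NK cells were higher than after DMSO. Cd7 was at 55.4 ± 12.2 and 313 ± 32.7 normalised read counts (log2 fold change 2.49, adjusted p = 8.22e-11), Il2rb at 95.5 ± 2.46 and 216 ± 18, and Cd27 at 3.65 ± 2.52 and 16 ± 5.99. Tbx21, which encodes the factor T-bet, was listed at 0 in all DMSO and ruxolitinib libraries and stood at 31.6 ± 7.5 after GSK-LSD1 and 38 ± 8.86 after the combination.

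Lymphocytes in the cultures could raise these genes, and would bring their other transcripts too. The summed value of Cd3e, Cd3d, Cd3g, Lck, Cd8a, Ncr1 and Gzma rose by 455% of the rise of Tbx21, which as first written met the bound set for T or NK cells. That rise of 144 rested on Gzma (599 ± 27.7 and 746 ± 141, adjusted p = 0.0556) and equalled the SD of the sum after GSK-LSD1. The reading was then changed, since this sum cannot tell T or NK cells from expression by the leukaemia cells. A narrower test was added afterwards: Cd3e, Cd3d and Cd3g together rose by 1.42% of the rise of Cd7 and at most 3.74% in any library. That argues against T cells and leaves NK cells open. Lck was at 90.5 ± 15.9 and 83.1 ± 8.35, and Ncr1 at 0 in all 12 libraries. These 7 genes stand in the lymphocyte list and in no other list here, and Gzma and Lck were already expressed after DMSO.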
